A study of Homo sapiens with 2 samples.

How the data were processed

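Poly(A)-selected RNA of H9 cells, an established human T cell lymphoma line, was sequenced from 1 library of untreated cells and 1 library of cells kept with doxorubicin for 6 h at 0.05 µM. The values analysed were raw read counts per gene symbol, deposited by the authors as whole numbers that were neither scaled nor corrected for length. The submitters' processing notes name HISAT2 as a tool, featureCounts as another, and hg19 as the genome build. Their versions, the gene annotation, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Such choices change the counts of genes that overlap another gene or have near-identical copies, and genes with at least 10% of their exons overlapped or of their sampled sequence shared are marked with that share where they are named. Smaller shares are not marked, and copies on the X and Y chromosomes of pseudoautosomal genes do not count towards them.

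The table held 19220 gene symbols, of which 4570 had 0 counts in both libraries. The untreated library summed to 33730703 counts and the treated library to 50174434, a depth ratio of 1.49. Counts were scaled by TMM effective library sizes from edgeR 4.0.16 in R 4.3.3. Each gene's log2 ratio of treated over untreated was computed after adding 0.5 to each count. An exact Clopper-Pearson binomial interval at 95% was computed for the ratio of the scaled counts. These intervals cover counting error only, because reads without molecular identifiers are not independent molecules and because no second culture of either condition was analysed here. A count of 0 allows up to 3 counts, which is 0.0911 CPM in the untreated library and 0.0584 in the treated library. Genes with at least 100 counts summed over both libraries were treated as measured, which left 11244.

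With 1 library per condition no dispersion can be estimated, so there is no test between conditions and no p-value across genes. A size rule was used in its place. A gene was counted as higher or lower when its ratio was at least 1.5-fold and the counting interval excluded a ratio of 1. The number of genes that would pass this rule without any treatment effect was simulated in 100 draws from the pooled expression of each gene. The draws used counting error alone, or counting error with an assumed coefficient of variation of 0.1 or 0.2 between cultures.

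Before the data were examined, 28 gene lists were fixed, covering DNA damage and p53 targets, cell cycle, apoptosis, T cell genes, stress responses, metabolism, translation, drug transport and markers of other cell types. For each list with at least 5 measured members, the median log2 ratio was computed with a 95% order-statistic interval over members. The median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these 2 libraries. The rule for named genes was fixed at the same time. It took the 12 highest and the 12 lowest ratios among genes past the size rule with at least 200 counts in the library where they were higher, leaving out clone-based and small RNA names. It also took, from each list, up to 2 highest and up to 2 lowest members past the size rule, or the 2 members with the most counts where none passed. CDKN1A, MDM2, TOP2A, TOP2B, ABCB1, CD4, CD3E and MYC were always included where measured. Some genes that the rule takes are not reported here.

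Gene-body length, transcript length, coding length and GC content came from GENCODE release 29, which is built on another assembly than the counts. Gene-body lengths, exon overlaps and membership of the pseudoautosomal region therefore refer to that assembly and may differ from the build used for the counts. Symbols or their synonyms matched 11043 of the 11244 measured genes, or 98.2%, and 11029 had every length. The same annotation gave the share of each gene's exons overlapped by other protein-coding genes on either strand. It also gave the share of a transcript's stretches of 50 bases, sampled every 25 bases, found in transcripts of other genes. Membrane-spanning segments were predicted from the coding sequence as windows of 19 residues with a mean Kyte-Doolittle hydropathy of at least 1.6.

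Alternatives fixed beforehand were the size factors of DESeq2 1.42.0, scaling by total counts, other count minimums, other size limits, a stricter counting interval, a larger added count and random lists without matching. After the data were examined, further alternatives were added. They adjusted the log2 ratios for transcript length with a lowess curve of span 0.3, or for transcript length, coding length and GC content with regression splines, or matched random lists on transcript length and expression. For ribosomal proteins and oxidative phosphorylation, an adjustment for coding length and GC content alone and a restriction to members with transcripts under 2000 bases were added, because the annotation gives some short genes long 3' untranslated regions. Hydropathy values came from Biopython 1.88. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6 were used. The scripts were tested on simulated data drawn for the comparison of treated with untreated cells. Of 11262 genes that reached the minimum there, 67 carried a planted 2-fold change and 100% of them were called. Among 66 genes with a planted 4-fold change 100% were also called, while 12 of 11062 unchanged genes were called. A planted 1.25-fold change, below the size limit, was called in 0% of 67 genes. The simulated counts held counting error alone, so the 12 calls leave out any variation between cultures. Of 200 random lists of unchanged genes, 6.5% lay outside percentiles 2.5 to 97.5. The counting interval held a ratio of 1 for 95.1% of the unchanged genes.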

Results

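The series measured the poly(A) transcriptome of H9 cells before and after exposure to doxorubicin. H9 is an established human T cell lymphoma line, and doxorubicin is an anthracycline that traps topoisomerase II on DNA. There was 1 untreated library, with 33730703 counts assigned to genes, and 1 library from cells exposed for 6 h to 0.05 µM doxorubicin, with 50174434 counts. The sample titles end in 1 and 2, and whether these are replicate numbers of separate sets of cultures or a running number is not given in the sources used here. The comparison asks which genes and pathways differ between exposed and unexposed cells. No value below has a replicate, the intervals of single genes cover counting error only, and the words higher and lower compare these 2 libraries.

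With doxorubicin, 52 of 77 cytosolic ribosomal protein genes and 24 of 48 oxidative phosphorylation genes were lower by the size rule. The list of cholesterol and SREBP target genes lay higher, with 11 of its 31 members past the size rule. Ribosomal protein mRNAs had a median log2 ratio of -0.73, and oxidative phosphorylation mRNAs one of -0.60. The cholesterol and SREBP target genes had a median of 0.29. Ratios were also higher for genes with longer transcripts across the table (Spearman's rho 0.55), and after adjustment for transcript length, coding length and GC content the medians were -0.25, -0.10 (-0.18 to 0.07) and 0.34. The p53 target genes had a median of 0.06 with an interval from -0.15 to 0.23. Among all 11244 measured genes, 816 were at least 1.5-fold higher and 1076 at least 1.5-fold lower with a counting interval that excluded a ratio of 1. Of these calls 43.1% were higher, and under total-count scaling, which gave 1084 higher and 852 lower, 56.0% were. Counting error alone gave on average 7.27 higher and 5.30 lower genes in the simulation, and an assumed coefficient of variation of 0.1 between cultures gave 65.1 and 62.3. An assumed coefficient of variation of 0.2 between cultures gave on average 935 higher and 927 lower genes with no treatment effect. The variation between cultures was not measured, so how many calls it would give is open.

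**Figure D1:**
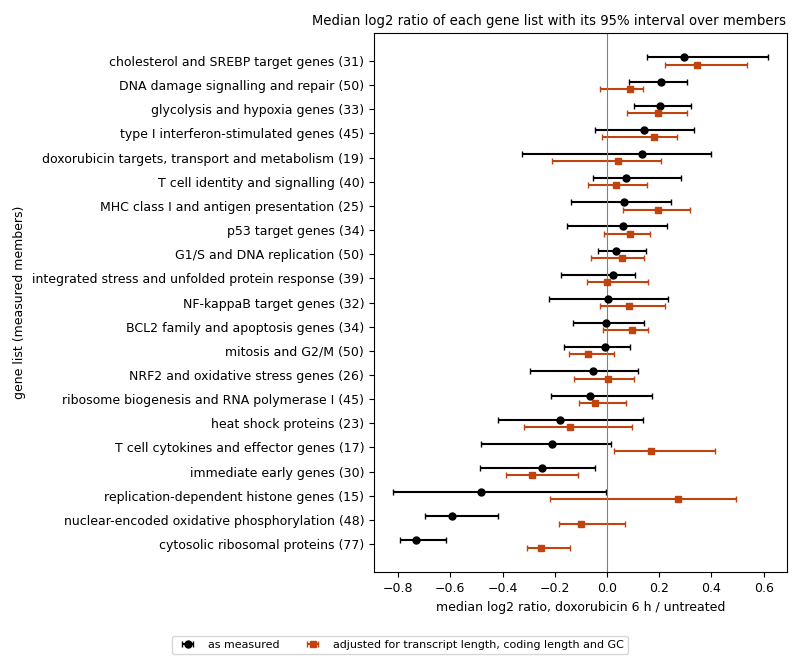
Median log2 ratio (horizontal axis, doxorubicin 6 h over untreated) of each gene list with at least 5 measured members (vertical axis), with its 95% interval over members, as measured (black circles) and after adjustment for transcript length, coding length and GC content (orange squares). Cytosolic ribosomal proteins lie at -0.73 as measured and -0.25 after adjustment, and cholesterol and SREBP target genes at 0.29 and 0.34.

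Of 77 measured cytosolic ribosomal protein genes, 52 were lower by the size rule, 0 were higher and 25 were neither. RPL37 was 2.20-fold lower (2.14 to 2.25) and RPL34, which shares 12.1% of its sampled stretches of 50 bases with other genes, was 2.08-fold lower (2.02 to 2.13). The list's median of -0.73 (-0.79 to -0.62) lay at percentile 0 of random lists matched on expression. In the list of nuclear-encoded oxidative phosphorylation genes, 24 of 48 were lower and 0 were higher. UQCRB, a subunit of complex III, was 2.31-fold lower (2.17 to 2.46), and COX7B, a subunit of cytochrome c oxidase, was 2.22-fold lower (2.08 to 2.37). Their median of -0.60 (-0.70 to -0.42) was also at percentile 0. The median transcript length was 1004 bases for the ribosomal proteins and 958 for oxidative phosphorylation, although the annotation gives some members long transcripts, such as 7686 bases for RPL37 and 5575 for UQCRB. After adjustment for transcript length, coding length and GC content, chosen after seeing the data, the ribosomal protein median was -0.25 (-0.31 to -0.14), with 10 members lower and 3 higher. That of oxidative phosphorylation was -0.10 (-0.18 to 0.07), with 2 lower and 0 higher, over the 39 members with a length, whose median without adjustment was -0.63. Over the 58 ribosomal protein genes with transcripts under 2000 bases the adjusted median was -0.11 (-0.25 to 0.02), at percentile 2.04. COX7B and RPL34 were no longer past the size rule, with adjusted log2 ratios of -0.17 and -0.34.

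Transcript length went with the ratio across the whole table. The median log2 ratio was -0.39 among the 2206 genes with the shortest transcripts (interquartile range -0.64 to -0.15) and 0.28 among the 2205 with the longest (0.06 to 0.50). By gene-body length, fixed beforehand as transcript length was, the medians of the 2206 shortest and the 2205 longest genes were -0.25 (-0.56 to 0.04) and 0.18 (-0.07 to 0.42). Spearman's rho across 11029 genes, which are not independent replicates, was 0.35 for gene-body length and 0.55 for the length of the longest transcript paired with RefSeq. With the median length of a gene's annotated transcripts it was 0.35. Of the 84 genes past the size rule that the naming rule took, 34 were no longer past it after adjustment for transcript length, coding length and GC content.

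**Figure D2:**
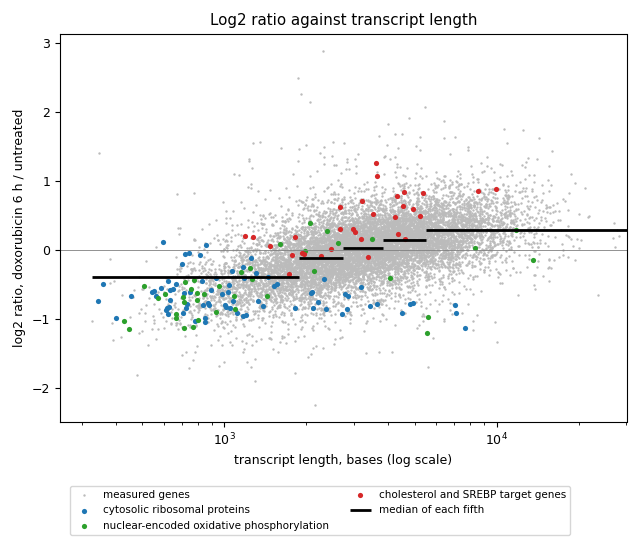
Log2 ratio of doxorubicin 6 h over untreated (vertical axis) against transcript length in bases (horizontal axis, log scale) for measured genes (grey), with 3 gene lists coloured and the medians of 5 equal groups by length as black lines. The medians run from -0.39 for the shortest group to 0.28 for the longest, and 2 of 11029 genes lie outside the plotted lengths.

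Cholesterol and SREBP target genes were higher in 11 of 31 measured members, lower in 0 and neither in 20. FADS2, a fatty acid desaturase, was 2.09-fold higher (2.01 to 2.18). The median of 0.29 (0.15 to 0.62) was at percentile 99.96, and the list's median transcript length was 3210 bases. After adjustment for length and GC content the median was 0.34 (0.22 to 0.54), with 6 members higher and 0 lower. Glycolysis and hypoxia genes had a median of 0.20 (0.10 to 0.32) at percentile 99.5, although only 2 of 33 were higher and 1 was lower. NDRG1 was 1.63-fold higher (1.44 to 1.84), PFKFB4, which sets fructose 2,6-bisphosphate levels, was 1.68-fold higher (1.27 to 2.27) and ANKRD37 was at a log2 ratio of -0.86 (-1.41 to -0.32), with 35.2% of its exons overlapped by another gene. The adjusted median of this list was 0.19 (0.07 to 0.31), and ANKRD37 was at -0.44, below the size limit.

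DNA damage signalling and repair genes had a median of 0.21 (0.08 to 0.31), and 0.1% of random lists matched on expression lay above it. By the size rule 5 of 50 were higher and 1 was lower. PRKDC, the catalytic subunit of DNA-dependent protein kinase, was 1.84-fold higher (1.79 to 1.89), BRCA2 was at a log2 ratio of 0.79 (0.68 to 0.92) and RPA3 was 1.56-fold lower (1.42 to 1.70). The median transcript length of the list was 4078 bases, and the adjusted median was 0.09 (-0.03 to 0.14) with 1 member higher and 0 lower. That median lay at percentile 98.2, and the list lay at 97.9 when matched on length and expression but at 80.8 after length alone. The adjusted log2 ratios of PRKDC, BRCA2 and RPA3 were 0.28, 0.45 and -0.26, below the size limit. Among p53 targets, 2 of 34 were higher, 3 were lower and 29 were neither, at percentile 73.1. TNFRSF10A, a death receptor for TRAIL, was 1.66-fold higher (1.48 to 1.86). RPS27L was 2.05-fold lower (1.80 to 2.34) and BBC3, which encodes PUMA, was 1.82-fold lower (1.71 to 1.92), but BBC3 was at a log2 ratio of -0.29 after adjustment, below the size limit. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, had 52 counts untreated and 84 treated, a log2 ratio of 0.05 (-0.46 to 0.58), so a difference within that range was not detectable at this depth. MDM2 was at 0.24 (0.18 to 0.30), not past the size rule, and at 0.008 after adjustment.

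Mitosis and G2/M genes had a median of -0.007 (-0.16 to 0.09) at percentile 28.6, with 1 of 50 higher and 2 lower, and lay at percentile 3.02 after adjustment for length and GC content. MKI67 was 1.81-fold higher (1.77 to 1.84), while NUF2, a kinetochore protein, was 1.80-fold lower (1.71 to 1.89) and UBE2C was 1.75-fold lower (1.69 to 1.82). Adjusted for length and GC content, MKI67 was at 0.26 and UBE2C at -0.36, below the size limit. G1/S and DNA replication genes had a median of 0.03 (-0.04 to 0.15) at percentile 62.1, with 2 of 50 higher and 0 lower. ORC1, of the origin recognition complex, was 1.65-fold higher (1.56 to 1.74) and MCM2, of the replicative helicase, was at a log2 ratio of 0.68 (0.65 to 0.71). Adjusted, they were at 0.55 and 0.49, below the size limit. Of 57 replication-dependent histone genes 42 were below the count minimum. The 15 measured members, 6 lower and 1 higher, had a median of -0.48 (-0.82 to -0.005) at percentile 0.12. The RNA was poly(A)-selected, so these values cover only polyadenylated transcripts of these genes. HIST2H2AC was 2.47-fold lower (1.94 to 3.16), HIST1H2AJ was 2.10-fold lower (1.41 to 3.15) and HIST1H2BN was 1.70-fold higher (1.10 to 2.75). HIST2H2AC and HIST1H2AJ share 28.6% and 78.6% of their sampled 50-base stretches with other genes, so their values are uncertain. Histone transcripts had a median length of 789 bases, and the adjusted median of the list was 0.27 (-0.22 to 0.50), of the opposite sign, with 2 members higher and 0 lower.

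Immediate early genes had a median of -0.25 (-0.49 to -0.05) at percentile 0.47, with 8 of 30 lower and 0 higher. The adjusted median was -0.29 (-0.39 to -0.11), with 5 lower and 0 higher. JUND, an AP-1 subunit, was at a log2 ratio of -1.26 (-1.32 to -1.20) and IER5L was 2.40-fold lower (1.63 to 3.61). MYC was at a log2 ratio of 0.37 (0.34 to 0.39). Interferon-stimulated genes had a median of 0.14 (-0.05 to 0.33) at percentile 97.4, with 7 of 45 higher and 5 lower. IFIT3 was 2.55-fold higher (1.63 to 4.29) from 23 and 93 counts, and HERC6 was 1.72-fold higher (1.45 to 2.06). ISG15 was 1.88-fold lower (1.79 to 1.97) and IFITM3, which shares 12.9% of its sampled stretches with other genes, was 1.75-fold lower (1.30 to 2.34). After adjustment for length and GC content 5 members of this list were higher and 0 lower, with ISG15 at -0.16 and IFITM3 at -0.24.

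Among T cell identity and signalling genes, 5 of 40 were higher and 1 was lower, with a median of 0.07 (-0.05 to 0.28) at percentile 82.7. CCR4, a skin-homing chemokine receptor, was 2.63-fold higher (2.44 to 2.83), CD3G of the T cell receptor complex was 2.16-fold higher (2.01 to 2.33) and TRAT1 was 1.67-fold lower (1.43 to 1.96), with an adjusted log2 ratio of -0.19. CD3E was at -0.33 (-0.38 to -0.29) and CD4 at 0.21 (0.08 to 0.34), and after adjustment they were at -0.07 and 0.11. T cell cytokine and effector genes had a median of -0.21 (-0.48 to 0.02) at percentile 5.84, with 2 of 17 higher and 4 lower. TNFRSF9 was 1.62-fold higher (1.53 to 1.71) and PRF1, which encodes perforin, was 1.51-fold higher (1.47 to 1.55). LTB was 2.03-fold lower (2.00 to 2.06) and IL32 was 1.83-fold lower (1.80 to 1.86). Their median transcript length was 1367 bases, and the adjusted median of the list was 0.17 (0.03 to 0.41), of the opposite sign, with 3 members higher and 0 lower. LTB was then at -0.44 and IL32 at -0.52, below the size limit.

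The list of doxorubicin targets, transport and metabolism had a median of 0.13 (-0.33 to 0.40) at percentile 88.1, with 3 of 19 higher and 0 lower. The export pumps ABCC4 and ABCC1 were 1.66-fold (1.53 to 1.80) and 1.57-fold (1.52 to 1.61) higher, and 0 members of the list passed the size rule after adjustment. ABCB1, the P-glycoprotein pump, had 0 counts in both libraries, which allows up to 0.0911 CPM untreated and 0.0584 CPM treated. TOP2A was at a log2 ratio of -0.04 (-0.07 to -0.01) and TOP2B at 0.16 (0.14 to 0.19), but TOP2A was at 0.025 under total-count scaling and TOP2B at -0.043 after adjustment, so neither has a settled direction. MHC class I and antigen presentation genes had a median of 0.07 (-0.14 to 0.24) at percentile 79.7. Of 25 members 2 were higher and 1 was lower, with ERAP1 1.53-fold higher (1.49 to 1.58), TAP2 1.55-fold higher (1.51 to 1.59) and PSMB10 1.58-fold lower (1.52 to 1.64). TAP2 and PSMB10 have 32.3% and 34.8% of their exons overlapped by other genes. The adjusted median of this list was 0.20 (0.06 to 0.32), while ERAP1 at 0.46, TAP2 at 0.32 and PSMB10 at -0.31 were then below the size limit.

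Stress lists held members on both sides before adjustment. Heat shock protein genes had a median of -0.18 (-0.42 to 0.14) at percentile 6.07, with 1 of 23 higher and 2 lower, HSPA8 1.62-fold higher (1.57 to 1.66) and HSPE1 2.15-fold lower (1.81 to 2.56). HSPA8 and HSPE1 share 15.5% and 27.0% of their sampled stretches with other genes, and HSPE1 was at a log2 ratio of -0.52 after adjustment, below the size limit. NRF2 and oxidative stress genes had a median of -0.05 (-0.30 to 0.12) at percentile 27.2, with 2 of 26 higher and 5 lower, and TXN, which encodes thioredoxin, was 1.99-fold lower (1.93 to 2.05), though at a log2 ratio of -0.28 after adjustment. Over the 25 members of this list with a length, 1 was higher and 0 were lower after adjustment. Genes of the integrated stress and unfolded protein responses had a median of 0.02 (-0.18 to 0.11) at percentile 66.4, with 3 of 39 higher and 1 lower. SLC7A11, the cystine transporter, was 1.63-fold higher (1.47 to 1.81) and CEBPB was at a log2 ratio of -1.26 (-1.32 to -1.19). NF-kappaB targets had a median of 0.003 (-0.22 to 0.23) at percentile 47.3, with 2 of 32 higher and 3 lower, among them REL, 2.22-fold higher (2.00 to 2.46), which shares 50.3% of its sampled stretches with other genes. BCL2 family and apoptosis genes had a median of -0.004 (-0.13 to 0.14) at percentile 43.6, with 3 of 34 higher and 3 lower, but 2 higher and 0 lower after adjustment. Ribosome biogenesis and RNA polymerase I genes had a median of -0.06 (-0.21 to 0.17) at percentile 13.01, with 4 of 45 higher and 1 lower, and UTP20 was 2.21-fold higher (2.03 to 2.40).

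Single genes were ranked by the naming rule, which needs at least 200 counts in the library where they were higher. The highest ratios among these belonged to BOP1, a ribosome biogenesis factor, which was 7.32-fold higher (5.84 to 9.41) from 78 and 896 counts, and to GTPBP6, which was 4.80-fold higher (4.30 to 5.39). PLCXD2 followed at 4.39-fold (3.08 to 6.62) and NCR3LG1, a ligand of the natural killer receptor NKp30, at 3.65-fold (3.35 to 3.98). The lowest were PPP2R3B, a phosphatase subunit, at 4.74-fold lower (4.36 to 5.16), C4orf48 at 3.52-fold lower (3.18 to 3.90) and TMEM158 at 3.45-fold lower (2.78 to 4.34). HES1, a Notch target, was 2.79-fold lower (2.40 to 3.26). After adjustment for length and GC content C4orf48 was at a log2 ratio of -0.56, below the size limit, while the other 11 of the 12 lowest and the 12 highest remained past the size rule. Of these 24 extreme genes, 10 had at least 10% of their exons overlapped or of their sampled stretches shared, among them ZBED6, with 96.0% of its exons overlapped, and NOMO2, with 92.3% of its stretches shared. Summed over its 3 near-identical copies, NOMO was 1.98-fold higher (1.92 to 2.05).

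**Figure D3:**
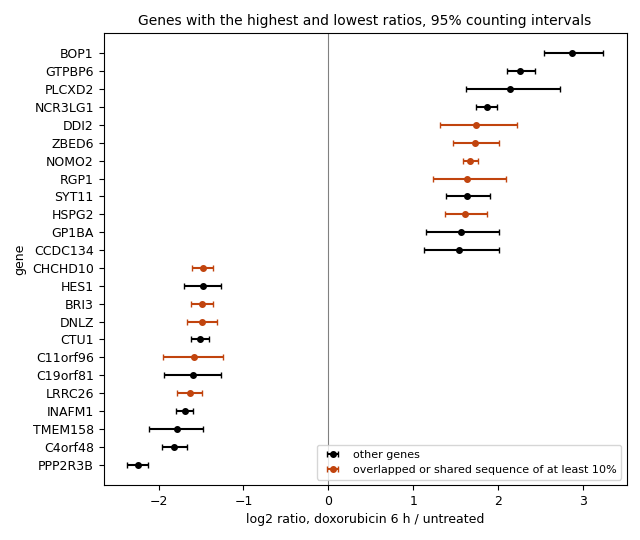
Log2 ratio of doxorubicin 6 h over untreated (horizontal axis) for the 12 highest and 12 lowest genes (vertical axis), with 95% counting intervals. Orange points mark the 10 genes with at least 10% overlapped exons or shared sequence; BOP1 lies at 2.87 and PPP2R3B at -2.25.

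Few of the listed markers of other cell types reached the count minimum, but some of those that did had many counts. Of the B cell markers 4 were measured, of which 1 was lower (FCER2, 2.53-fold, 2.05 to 3.14) and 3 were neither. Myeloid markers had 2 measured members, CD68, 1.65-fold higher (1.19 to 2.36) with 91.9% of its sampled stretches shared with other genes, and CST3, 1.52-fold lower (1.18 to 1.96), with an adjusted log2 ratio of -0.42. Epithelial and fibroblast markers had 4 measured members, none past the size rule, and ACTA2, with 12.8% of its exons overlapped by other genes, had 70911 counts untreated and 77435 treated. Embryonic stem cell markers likewise had 4 measured members with 0 past the size rule, and erythroid markers had 0 measured members. Of the 21 genes of the snoRNA host list, 1 was among the gene symbols with counts, TAF1D, at a log2 ratio of -0.31 (-0.41 to -0.21). Of the 13 mitochondrially encoded transcripts, 0 were among those symbols under the names searched, so they could not be analysed.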

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

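The adjustments for transcript length, and the matching of random lists on it, were chosen after seeing the data. No paired analysis was possible because each condition had 1 library, and for the same reason no replicate could be left out. With the 2-fold limit 128 genes were higher and 175 lower, and with the smaller limit 2294 and 2416, by construction. Adjusted for transcript length, 544 were higher and 503 lower (52.0% higher); adjusted also for coding length and GC, 493 were higher and 366 lower (57.4% higher), of which 344 and 274 were also called without adjustment. DESeq2 size factors and total counts kept every list median inside its interval.

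For list medians after transcript length alone and after all 3 properties, the values were 0.26 and 0.27 for histone genes and 0.13 and 0.17 for T cell cytokines, both of opposite sign to the unadjusted medians, -0.071 and -0.10 for oxidative phosphorylation and -0.17 and -0.25 for ribosomal proteins. DNA damage genes moved to 0.046 and MHC genes to 0.34 after length alone. Percentiles under the same pair of adjustments were 94.8 and 96.6 for histone genes, 99.79 and 99.88 for interferon-stimulated genes and 100 and 99.96 for MHC genes. After length alone DNA damage genes lay at 80.8 (98.2 after all 3 properties, 97.9 matched on length and expression) and oxidative phosphorylation at 7.44, and after all 3 properties T cell cytokines lay at 98.4 and heat shock genes at 2.28. Matched on length and expression, histone genes lay at 20.8, interferon-stimulated genes at 99.79 and MHC genes at 99.98. With a minimum of 20 counts immediate early genes lay at 2.60 and interferon-stimulated genes at 98.8, the latter at 99.2 with a minimum of 400 and at 97.9 with 5 added to each count. Adjusted for coding length and GC alone, ribosomal proteins lay at -0.33 (percentile 0) and oxidative phosphorylation at -0.17 (percentile 0.02), and over members with transcripts under 2000 bases at -0.11 and -0.10 (percentiles 2.04 and 2.56). After all 3 properties the ratio of CCL20 turned sign, to 0.22, as did TOP2B and DNMT3B, which had not passed the size rule. Spearman's correlation with gene-body length was 0.35 and with transcript length 0.55, and after adjustment 0.013 and 0.021. Beyond the construction of each adjustment, the cause was not tested. Depth limits genes with few counts, such as CDKN1A.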

Other observations

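The tests in this part were chosen after their results, or results close to them, had been seen, except the correlation with transcript length, so each reading is a hypothesis about these 2 libraries. Groups defined by gene name, some picked because members had high ratios, extended the description. Mitochondrial ribosomal protein genes had a median log2 ratio of -0.46 over 77 genes, with 22 lower and 0 higher, and proteasome subunit genes one of -0.30 over 47, with 9 lower and 2 higher. Solute carrier genes had a median of 0.15 over 195 genes, with 22 higher and 6 lower. Chemokine receptor genes had one of 0.42 over 6, with 3 higher and 0 lower. After adjustment for transcript length, coding length and GC content these medians were -0.05, -0.10, 0.14 and 0.47. Zinc finger genes had a median of 0.06 over 385 (0.013 adjusted), GPI anchor synthesis genes 0.06 over 21 (0.18 adjusted) and N-glycosylation genes -0.14 over 23 (0.058 adjusted, of opposite sign). SHOX2 had 0 counts untreated and 34 treated, below the minimum of 100 for a measured gene. Its ratio over a floor of 3 counts was 7.27-fold, which leaves out the counting error of the 34.

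TFRC, the transferrin receptor, was also named after its values were seen, at 2.36-fold higher (2.27 to 2.46). Genes whose proteins have at least 3 predicted membrane segments had a median log2 ratio of 0.19 (0.14 to 0.22) over 943 genes, against -0.04 (-0.05 to -0.03) over 7562 genes with 0 segments.

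The lower medians of the ribosomal protein and oxidative phosphorylation lists went with a table-wide relation to transcript length. For the ribosomal protein list, the adjusted median of -0.25 (-0.31 to -0.14) stayed at percentile 0. Matched on length and expression, this list also lay at percentile 0, with its -0.73 against a random median of -0.44. Over the 58 genes with transcripts under 2000 bases the adjusted median was -0.11 at percentile 2.04, with an interval from -0.25 to 0.02. Adjustment thus made the median of the full list smaller without removing it. Whether length and GC content are the whole cause stays open, because the interval over the short members holds 0. For oxidative phosphorylation, length and GC content cannot be told apart from an effect on the list. Its adjusted median of -0.10 lay at percentile 1.23, with an interval (-0.18 to 0.07) that holds 0. The list lay at percentile 7.44 after length alone, 0.02 after coding length and GC and 0.03 when matched on length and expression. Gene-body length held little further relation with the ratio once transcript length, coding length and GC were removed (rho 0.013). That step also removes whatever gene-body length shares with them, and no adjustment for gene-body length was made. It therefore cannot decide which length is the source of the relation. A difference in RNA integrity or library preparation may give a rho of 0.55 with transcript length, and with 1 library per condition it cannot be told apart from the treatment.

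The higher median of genes for membrane proteins was smaller after adjustment for length and GC content, but was not removed. The adjusted median of genes with at least 3 segments was 0.13 (0.11 to 0.15), at percentile 100 of 1000 random lists. Of these genes 8.27% were then higher and 2.97% lower by the size rule, against 3.23% and 3.45% of genes with 0 segments. Cholesterol and SREBP target genes include many membrane proteins, but the 8 members with 0 predicted segments had an adjusted median of 0.37 at percentile 99.95, which argues against membrane location as the whole cause. A response of sterol synthesis to the drug is a candidate explanation that stays open, as does a difference between the cultures in density or medium, since neither was tested.

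The extreme ratios of single genes may partly reflect how reads were assigned. Overlapped exons or shared sequence marked 10 of the 24 genes, at percentile 98.8 of random lists matched on expression, which had a median of 5. The mark is a share of exon or transcript length, and these random lists were not matched on length. The excess therefore cannot decide between read assignment and transcript length. GTPBP6 and PPP2R3B both lie in the pseudoautosomal region, and their opposite directions argue against 1 shift of the whole region as the cause of both ratios. The other 8 measured genes of the region had a median log2 ratio of 0.38, against 0.007 over all measured genes. Its interval (-0.22 to 0.57) spans the lowest to the highest of the 8, so a smaller rise of the region is not excluded. GTPBP6 and PPP2R3B each have a copy on the Y chromosome that the shared share does not count. Different handling of reads with several alignments in the 2 libraries therefore stays open for them. BOP1, the highest, had 0% overlapped exons and shared stretches in the annotation used here, which is of another build than the counts, so its ratio stays open.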
